A study of Mus musculus with 48 samples.

How the data were processed

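RNA-seq libraries of 24 clonal mouse bone marrow cultures were measured in 2 states, 48 libraries in all. The group of each library was taken from its sample labels, which name granulocyte-monocyte progenitors or monocytic cells as the source, and its clone from the number in its title. What the words plus and minus in the titles stand for is not given in the sources used here. The labels' protocols name RPMI medium, serum and stem cell factor for growth, column extraction of RNA and kit-made libraries. The series design text says that cultures of the 2 states are matched by clone, so clone was the block in all fits. As a check, 18 of 24 clones had a correlation above 0.1 between the deviations of their 2 libraries from the group means. These means run over all clones, so the difference between the sets of clones raises the count: with each set centred it was 14, 3 of 13 in clones 1 to 13 and 11 of 11 in clones 15 to 26, so in the first set the pairing rests on the labels and the design text. Without the replicate block limma called 7436 genes in place of 7623.

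The authors deposited 1 table of TPM (length-corrected transcript abundances relative to the library total) per gene symbol, with 34643 rows and 48 sample columns. Salmon was used for quantification and mm10 was the build, per the submitters' processing notes. The annotation release and the way transcripts were summed to genes are not given in the sources used here. The deposited TPM columns summed to between 982949 and 999250. TPM keep no depth, so no counting error could be given, and an exact 0 can be a failed estimate. Salmon divides reads among near-identical copies, so Ly6c2 and Ly6c1, the Stfa genes, Mcpt8, the H2 genes, and Pgk1 and Pgk1-rs7 are uncertain. TPM are relative, so a large class of transcripts that grows in a library lowers all others. Mitochondrial transcripts took 1.98 to 25.1% of TPM in monocytes, and gene models named Gm took a mean of 32.0% in progenitors and 23.5% in monocytes. A total of 26 rows whose name was a calendar date, a sign of spreadsheet conversion, were left out. No pair of libraries was identical, and the highest correlation between libraries was 0.986.

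Gene changes between states were tested with limma 3.58.1 in R 4.3.3 on log2(TPM + 1) with clone as a block and a mean-variance trend, two-sided. Genes with a mean TPM of at least 1 entered (11072), with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(TPM + 1) scale and understate the change of low genes. A total of 359 genes in 28 lists were fixed from general knowledge, and 358 were in the table. Lists were tested with camera at a preset correlation of 0.01 and with an estimated correlation. They were also tested with fry, a rotation test of the members of a list alone that allows for correlation between them. List genes that passed the filter of a mean TPM of at least 1 are called measured. One list with 1 measured gene had no camera test.

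Differences between clones were followed across states by Pearson correlation of log2(TPM + 1) per gene, with a one-sided permutation test of 100000 pairings, for 9570 genes with a mean TPM of at least 1 and an SD of at least 0.25 in both states. Whole profiles were compared over the 1000 most variable genes. List scores were means of z-scores over lists with at least 4 measured genes, compared by two-sided permutation tests, exact with fewer than 10 clones. Each correlation was repeated without the 2 clones farthest from the median. Values with a gap of over 40% of the range and at least 2 clones on each side were called separate clusters and given no pooled correlation. Unequal spread was tested by 100000 swaps of state within clones for 6329 genes with a mean TPM of at least 5 in both states. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9 were used.

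On simulated data, limma recovered 34.3, 91.0 and 100% of genes changed by 0.5, 1 and 2 log2 units among 11072, with 11 false calls. The test of shared clone differences recovered 17.9, 76.1 and 100% of genes with a true correlation of 0.5, 0.7 and 0.9 among 9570, with 7 false calls. The test of spread recovered 28.4, 88.1 and 98.5% of genes with an SD ratio of 2, 3 and 4 among 6329, with 10 false calls. These counts hold for the simulated settings only. The limma simulation drew genes independently and without sets of clones, so its false calls do not give the error rate in the real data.

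Groups, tests, gene lists, the rule for named genes and the first alternatives were chosen before the data were examined. Between states the rule took the 5 genes with the largest change in each direction that passed, moved the same way in at least 22 of 24 clones and reached a mean of 10 TPM in the higher group, then up to 2 passing genes per list with the largest change, and Hoxb8. For shared clone differences it took the 10 highest correlations among passing genes with an SD of at least 0.5 and a mean of at least 5 TPM in both states, 5 genes with separate clusters as values only, and up to 2 per list. For spread it took the 5 largest SD ratios in each direction. Gene models, pseudogenes by name and mitochondrial genes were left out of the top genes. Ccr2, Clec4e, Il6, Mpo, Nkg7, H2-DMb1, H2-Ab1, H2-DMa, H2-Oa, Itgax, Tcf4, Ebf1 and Ly6g, and Esr1 between states, were named after their values were seen.

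Other settings chosen in advance were pseudocounts of 0.1 and 5, other filters, TPM rescaled by median-of-ratios size factors, no replicate block, clone as a random effect, a signed-rank permutation test, Spearman correlation, other gene numbers for the profiles, medians for the scores, and removal of the cell cycle score or the first principal component. After seeing the data, each set of clones was centred or taken alone, clones 19, 21, 24 and 26 were left out because each holds a library that stands apart, clones 8 and 20 were left out because their monocyte libraries go against their sets in Pgk1-rs7, and mitochondrial, Gm and pseudogene rows were removed with the rest rescaled. The interaction of state and set, the tests without clone 8 or clone 20 alone, the differences between the sets in list score correlations and the placing of each monocyte library between the sets, and the neutrophil score without clones 15, 16, 20 and 21 and against the share of monocyte-state genes, were also chosen after seeing the data. The sets are the clone numbers 1 to 13 and 15 to 26, with no 14 or 25 among the samples. Coordinates are 1-based and come from GENCODE M21 on GRCm38, the assembly that mm10 names, where 97.2% of row names were found as symbols.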

Results

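RNA was sequenced from 24 clonal cultures of mouse bone marrow cells, each measured once as a progenitor culture and once as a monocytic culture, giving 48 libraries. ER-Hoxb8 cells are conditionally immortalised myeloid progenitors: a fusion of the estrogen receptor hormone-binding domain with the homeobox factor Hoxb8 holds them in a dividing progenitor state, and loss of its activity lets them mature. The labels describe one library of each clone as granulocyte-monocyte progenitors (here progenitor, n = 24) and the other as monocytic cells (here monocyte, n = 24). The clones carry the numbers 1 to 13, 15 to 24 and 26. The values were TPM, length-corrected transcript abundances relative to the library total, which keep no sequencing depth, so the depth of each library was unknown. Genes with at least 1 TPM numbered 8240 to 11030 in the progenitor libraries and 9436 to 10717 in the monocyte libraries.

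Summed over 11072 genes, state took 40.3% of all sums of squares, clone took 34.3% and the rest 25.4%. For the median gene the shares were 21.7%, 40.7% and 31.3%. State has 1 degree of freedom and clone and the rest have 23 each, so clone would take as much as the rest if clones did not differ, and the shares do not rank clone against state. The first principal component, with 45.1% of the variance, parted the states, and the third, with 7.85%, parted clones 1 to 13 (n = 13) from clones 15 to 26 (n = 11). The labels name no batch, and these sets were seen only in the data. Mitochondrial transcripts took 5.73% ± 1.44 (SD, n = 13) of TPM in progenitors of clones 1 to 13 and 11.96% ± 2.06 (SD, n = 11) in those of clones 15 to 26. Some libraries stood apart: progenitor clone 21 had 23247 genes at 0, progenitor clone 24 had 8240 genes with at least 1 TPM, and monocyte clone 26 held 25.1% of its TPM in mitochondrial transcripts.

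The first comparison asked how gene expression changed between the progenitor and the monocyte culture of the same clones. Monocytes held very high levels of transcripts for granule and antimicrobial proteins that progenitors held at low levels. Chil3, a chitinase-like protein of myeloid cells, rose from 56.3 ± 118 to 9310 ± 6166 TPM (SD, n = 24 each), a log2 fold change of 9.55 (SE 0.64, adjusted p = 3.81e-13). S100a8 and S100a9, the subunits of calprotectin, rose by 9.43 and 9.42, Ltf, the iron-binding granule protein lactoferrin, by 8.91, and Stfa1, a cysteine protease inhibitor, by 8.90, each in 24 of 24 clones. The steepest falls were those of the progenitor surface protein Cd34 (417 ± 147 to 6.79 ± 4.22 TPM, log2 fold change -5.85, SE 0.19, adjusted p = 9.66e-20), the mast cell protease Cpa3 (-5.75), Ctla2a (-5.40) and the adhesion receptors Adgrg1 (-4.88) and Adgrl4 (-4.70). All 5 fell in 24 of 24 clones. Stfa1 belongs to a family of near-identical copies and its level is uncertain for that reason. On mouse build mm10, Chil3 lies on chromosome 3 from 106147554 to 106167564 and Cd34 on chromosome 1 from 194938819 to 194961279, both annotated as protein-coding.

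Of 11072 genes tested with limma and clone as a block, 7623 changed at an adjusted p under 0.05, 3584 higher and 4039 lower in monocytes. At least 2-fold changes numbered 3245, of which 1768 were higher in monocytes. In clones 15 to 26 alone 5005 genes passed, 1974 higher and 3031 lower, while in clones 1 to 13 alone 4301 were higher and 3635 lower. Once mitochondrial, Gm and pseudogene entries were left out and the rest rescaled, 2974 genes were higher and 4823 lower, and of the 2-fold changes 1515 were higher and 2135 lower. The median change over all genes was -0.06, and -0.25 without those entries, so small changes are relative to that shift. Its sign turned between the sets, with 0.08 in clones 1 to 13 and -0.22 in clones 15 to 26. With a pseudocount of 5 the 2-fold changes fell to 1826.

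Genes of the progenitor state fell. All 10 measured stem and progenitor genes fell, with a median log2 fold change of -3.06. Flt3, a cytokine receptor of early progenitors, went from 19.3 ± 7.89 to 0.0664 ± 0.0529 TPM (log2 fold change -4.12, SE 0.14). The list ranked below other genes by camera (adjusted p = 6.15e-07), but not with an estimated correlation (adjusted p = 0.218). Ribosome biogenesis genes fell in 15 of 15 cases. Dkc1, a pseudouridine synthase, changed by -3.07 and the snoRNP protein Nop58 by -2.73 (camera adjusted p = 1.64e-07, and adjusted p = 0.239 with an estimated correlation). Of 22 cell cycle genes 17 fell and none rose, led by the replicative helicase subunits Mcm7 (-1.79) and Mcm6 (-1.72). That list passed camera (adjusted p = 0.00766) and did not with an estimated correlation (adjusted p = 0.656). Of 14 oxidative phosphorylation genes 10 fell, among them the ATP synthase subunits Atp5b (-0.96) and Atp5a1 (-0.82), with camera adjusted p = 0.0405 and adjusted p = 0.631 with an estimated correlation.

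Neutrophil and monocyte genes rose together. All 20 measured secondary granule and neutrophil genes rose, with a median of 5.15 (camera adjusted p = 1.97e-11, adjusted p = 0.221 with an estimated correlation). Of 18 classical monocyte genes 15 rose and 1 fell, and adjusted over the list alone 16 rose and 1 fell. Lyz2, the lysozyme of monocytes and neutrophils, went from 140 ± 170 to 9113 ± 4686 TPM (log2 fold change 6.60, SE 0.32). Ly6c2, a surface marker of classical monocytes that shares sequence with Ly6c1, rose by 6.07 (SE 0.64) in 23 of 24 clones. The gene that fell was the chemokine receptor Ccr2 (64.2 to 38.3 TPM, log2 fold change -0.97). The list passed camera (adjusted p = 1.64e-07) and did not with an estimated correlation (adjusted p = 0.221). Of 9 non-classical monocyte genes 7 rose and 1 fell (7 and 2 adjusted over the list alone), with the apolipoprotein Apoc2 at 6.95 and the fractalkine receptor Cx3cr1 at 2.82 (camera adjusted p = 0.00766, adjusted p = 0.221 with an estimated correlation). All 14 macrophage genes rose, including Gpnmb (5.94) and the lipid receptor Trem2 (5.71), with camera adjusted p = 1.64e-07 and adjusted p = 0.221 with an estimated correlation.

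**Figure D1:**
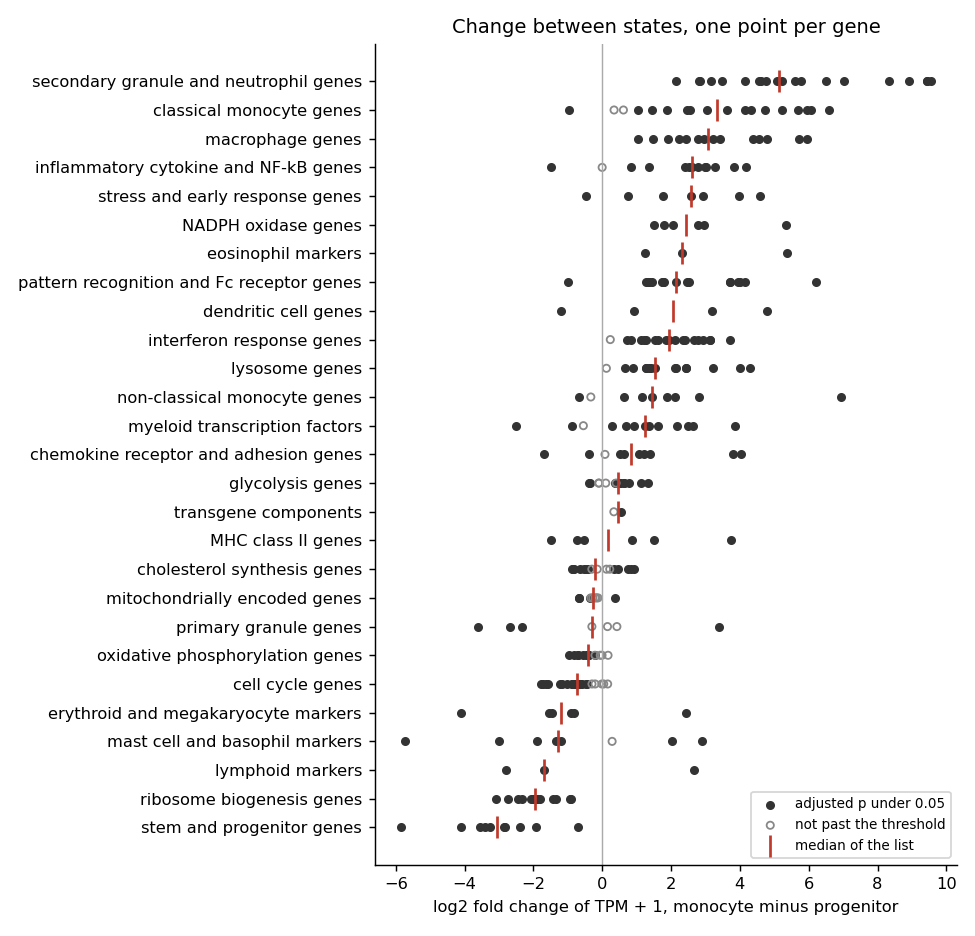
Log2 fold change of TPM + 1 (x axis, monocyte minus progenitor, 24 clones) for each measured gene of 27 lists (y axis); filled points passed an adjusted p of 0.05 and red bars are list medians. Medians ran from -3.06 for stem and progenitor genes to 5.15 for secondary granule and neutrophil genes.

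Effector genes of phagocytes also rose. All 6 NADPH oxidase genes rose, led by the catalytic subunit Cybb (5.34) and its partner Cyba (2.96), with camera adjusted p = 1.98e-05 and adjusted p = 0.218 with an estimated correlation. Of 15 lysosome genes 14 rose and none fell. The protease Ctsb changed by 4.30 and the saposin precursor Psap by 4.01 (camera adjusted p = 1.64e-07, adjusted p = 0.221 with an estimated correlation). Of 17 pattern recognition and Fc receptor genes 16 rose, such as the lectin Clec4n (6.22) and the RNA sensor Tlr7 (4.14), and the lectin Clec4e fell (191 to 108 TPM, adjusted p = 2.00e-04). That list had camera adjusted p = 7.56e-08 and adjusted p = 0.221 with an estimated correlation. Of 13 inflammatory cytokine and NF-kB genes 11 rose, with the interleukin 1 receptor antagonist Il1rn at 4.19 and the chemokine Ccl2 at 3.84, and Il6 fell from 3.17 to 0.196 TPM (camera adjusted p = 9.68e-05, adjusted p = 0.221 with an estimated correlation). Of 19 interferon response genes 18 rose, led by Irf7 (3.70) and Isg15 (3.14), and monocyte clone 15 stood apart with 1948 TPM of Irf7, where the other monocytes had at most 118 TPM. The list had camera adjusted p = 4.58e-06 and adjusted p = 0.340 with an estimated correlation. Of 10 chemokine receptor and adhesion genes 7 rose and 2 fell, with the integrin Itgb2 at 4.02 and Ccr1 at 3.81 (camera adjusted p = 0.0405, adjusted p = 0.419 with an estimated correlation). Of 13 myeloid transcription factors 10 rose and 2 fell, with Klf2 at 3.87 and Klf6 at 2.62 (camera adjusted p = 0.00790, adjusted p = 0.272 with an estimated correlation). Of 7 stress and early response genes 6 rose and 1 fell, with heme oxygenase Hmox1 at 4.59 and Atf3 at 3.97 (camera adjusted p = 0.00215, adjusted p = 0.239 with an estimated correlation).

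Other lists moved both ways and did not pass camera. Of 7 primary granule genes Elane, neutrophil elastase, rose (53.7 ± 143 to 276 ± 269 TPM, log2 fold change 3.39, SE 0.82), while Ctsg, cathepsin G, fell (-3.62) together with Mpo (-2.33) and Nkg7 (-2.69). Camera gave that list an adjusted p of 0.450. Among 6 genes of MHC class II, the invariant chain Cd74 (3.75), H2-DMb1 (0.86) and H2-DMb2 (0.975 to 4.61 TPM) rose and H2-Ab1 (-1.49), H2-DMa (-0.73) and H2-Oa (-0.54) fell (camera adjusted p = 0.516). Of 4 dendritic cell genes Id2 (4.79), the lectin Clec10a (3.18) and Itgax (0.93) rose and Tcf4 fell (-1.20), with camera adjusted p = 0.117. Of 14 glycolysis genes 8 rose and 2 fell, with Pkm at 1.33 and Hk2 at 1.13 (camera adjusted p = 0.121). Of 16 cholesterol synthesis genes 5 rose and 7 fell, with Sc5d at 0.92 and Dhcr7 at -0.87 (camera adjusted p = 0.787). Of 9 mitochondrially encoded genes 1 rose and 3 fell (1 and 2 adjusted over the list alone), with mt-Nd1 at -0.68 and mt-Nd2 at -0.67 (camera adjusted p = 0.394).

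Markers of other lineages moved both ways. Of 8 mast cell and basophil markers 5 fell and 2 rose: Cpa3 went from 1306 ± 552 to 60.4 ± 93.4 TPM and Mcpt8 changed by -2.99 (camera adjusted p = 0.384). All 3 measured eosinophil markers rose, with the granule protein Prg2 going from 6.51 ± 22.1 to 253 ± 323 TPM (log2 fold change 5.38, SE 0.52) and Prg3 changing by 2.32. That list had camera adjusted p = 0.0443 and adjusted p = 0.340 with an estimated correlation. Of 6 erythroid and megakaryocyte markers 5 fell, among them Itga2b (-4.10), and Vwf rose (2.44), with camera adjusted p = 0.134. Of 3 lymphoid markers the terminal transferase Dntt (-2.80) and Ebf1 (-1.70) fell and Il7r rose (2.67), with camera adjusted p = 0.516. The only stromal marker past the filter on mean TPM, Pdgfrb, fell (-1.37). In the other lists, counts adjusted over the list alone equalled those over all genes tested.

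Hoxb8, the factor that holds these cells in the progenitor state, differed little between states over all clones, and its call depended on the setting. It measured 183 ± 173 TPM in progenitors and 208 ± 125 TPM in monocytes (log2 fold change 0.56, SE 0.21, adjusted p = 0.0192), higher in monocytes in 17 of 24 clones. It no longer passed without clone as a block (adjusted p = 0.116), with clone as a random effect (adjusted p = 0.0822), or without mitochondrial, Gm and pseudogene entries (log2 fold change 0.31, adjusted p = 0.187). Of the 2 transgene components it alone passed with the block, and the list had camera adjusted p = 0.502. Within clones 1 to 13 it went from 60.0 ± 22.3 to 149 ± 56.7 TPM (log2 fold change 1.27), and within clones 15 to 26 from 328 ± 160 to 278 ± 150 TPM (log2 fold change -0.28). The difference between the sets was -1.55 (SE 0.30, adjusted p = 0.00180). Esr1 showed the same pattern, with log2 fold changes of 0.96 and -0.40 and a difference of -1.36 (SE 0.26, adjusted p = 0.00176). Hoxb8 lies on chromosome 11 from 96281905 to 96285315 of mm10, and the TPM do not separate the gene from a transgene.

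Many genes changed by different amounts in the 2 sets of clones. Tested as an interaction in limma, 1268 of 11072 genes passed, 48 of them called in opposite directions. The count rose to 2429 without clone 8 and to 2938 without clones 19, 21, 24 and 26, with 1268 and 1211 genes shared with the first. Of the 60 genes that the rule named between states 16 passed, all with the smaller change in clones 15 to 26 (adjusted p from 0.00148 to 0.0450). The rule picks large changes and leaves out the genes named later, so this direction does not speak for all 1268 genes. Ltf rose by 11.24 on the log2 scale in clones 1 to 13 and by 6.15 in clones 15 to 26, Gpnmb by 7.67 and 3.89, and Lyz2 by 7.59 and 5.43. Progenitors differed between the sets in 4362 genes and monocytes in 787.

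**Figure D2:**
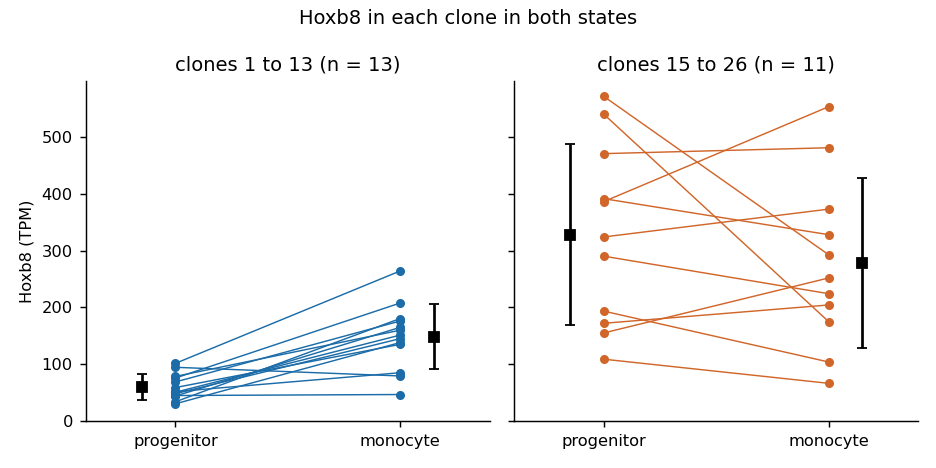
Hoxb8 in TPM (y axis) in the progenitor and monocyte library of each clone (joined points), for clones 1 to 13 (left) and clones 15 to 26 (right); black squares are means with SD. Progenitors of clones 1 to 13 lay between 30.1 and 101 TPM and those of clones 15 to 26 between 109 and 572 TPM.

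Measuring both states of each clone also allowed the question whether a difference between clones seen in progenitors was kept in monocytes. Pak1, a kinase of cytoskeletal signalling, went with itself across states: its level ran from 0.690 to 29.0 TPM among progenitors and from 1.04 to 82.3 TPM among monocytes (r = 0.856, adjusted p = 0.00281, rho = 0.775, both one-sided permutation p = 1e-05, the smallest 100000 pairings give, n = 24). Without the 2 farthest clones r was 0.784, and within the sets it was 0.523 for clones 1 to 13 and 0.899 for clones 15 to 26. The nucleosome-binding protein Hmgn1 (r = 0.810, rho = 0.677, 0.824 and 0.804 within the sets, 0.641 without the 2 farthest clones) ran from 9.84 to 583 TPM among progenitors. The reductase Akr1c13 (r = 0.834, rho = 0.803) and the chromatin remodeller Chd9 (r = 0.802, rho = 0.803) had r above 0.5 in both sets. S100a11 (r = 0.797), Tmsb4x (0.778) and Map7 (0.771) had r of 0.970, 0.739 and 0.837 within clones 15 to 26 and of -0.49, -0.02 and -0.06 within clones 1 to 13. For Safb2 (0.803) and Stk11 (0.773) r was 0.298 and 0.344 within clones 15 to 26. Renbp (0.768) rested on 2 clones, since r was 0.428 without them.

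In all, 353 of 9570 genes passed (Benjamini-Hochberg over genes, adjusted p under 0.05). The count depended on the sets: with each set centred 32 genes passed, within clones 15 to 26 alone 23, and within clones 1 to 13 alone 0, where 477 genes had an unadjusted p under 0.05. That is about the number that chance gives over 9570 genes, and the median r within clones 1 to 13 was -0.05. Members of the fixed lists that passed included Hoxb8 (r = 0.617, 0.198 and 0.661 within clones 1 to 13 and 15 to 26) and Esr1 (0.580, 0.149 and 0.691). The neutrophil gene S100a9 passed over all clones (0.504) with r of -0.39 and 0.849 within the sets. H2-Ab1 (0.591, 0.599 and 0.645) held a like value in both sets, as did mt-Nd5 (0.687, 0.531 and 0.630) and mt-Nd2 (0.608, 0.403 and 0.648). Idi1 (0.754), Pgk1 (0.724), Ldha (0.693) and Ddit3 (0.690) had r of 0.327 or less within either set. Some genes fell into separate clusters and were given no pooled r. Pgk1-rs7, annotated as a processed pseudogene of the glycolytic kinase gene Pgk1, ran from 58.3 to 142 TPM in progenitors of clones 1 to 13 and was listed at 0 in all 11 progenitors of clones 15 to 26. Rsrp1 ran from 12.9 to 21.6 TPM in progenitors of clones 1 to 13 and from 19.1 to 300.0 TPM in those of clones 15 to 26. Ifi27 was at 0.0494, 0.544 and 0.606 TPM in progenitor clones 17, 1 and 11, against a mean of 49.9 TPM, and at 0.451, 3.19 and 22.5 TPM in their monocytes, against a mean of 102 TPM. Slpi ran from 5.37 to 655 TPM, Stfa2 from 0 to 103 TPM and the integrin gene Itgb2l from 0 to 24.4 TPM among progenitors.

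The whole profile of a clone was then matched between states. In clones 15 to 26 the monocyte profile resembled the progenitor profile of the same clone. Over the 1000 most variable genes, 7 of 24 monocyte profiles correlated best with their own progenitor, with a mean own correlation of 0.192 against 0.00338 for permuted pairings (one-sided permutation p = 1e-05, the smallest possible). Within clones 15 to 26, 9 of 11 clones matched their own partner (mean own r = 0.243, permutation p = 1e-05). Within clones 1 to 13 the count was 1 of 13 (mean own r = 0.0192, permutation p = 0.191). Without clone 8 the count was still 1 of 12 and the mean own r was 0.0407, now with a permutation p of 0.0256. The difference of 0.224 between the sets had a two-sided permutation p of 1e-05, and without clone 8 it was 0.205 with the same p.

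**Figure D3:**
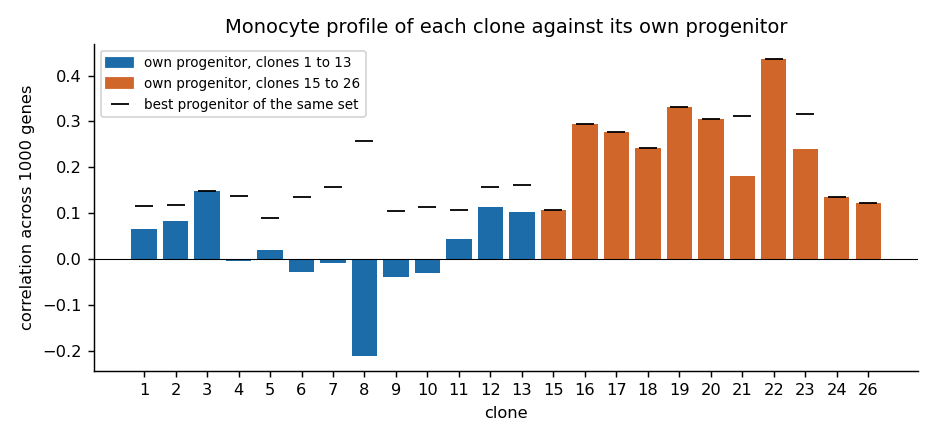
Correlation (y axis, 1000 genes) of each clone's monocyte profile with its own progenitor profile (bars), both centred within the set of clones, and with the best progenitor of the same set (dashes); clones on the x axis. Own correlations ran from -0.21 in clone 8 to 0.437 in clone 22.

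Scores of gene lists were compared between states over the clones, for 24 lists. None passed the correction over all 24 clones. The lowest adjusted p was 0.171, for primary granule genes (r = -0.53, rho = -0.45, p = 0.00711 and 0.0263, two-sided permutation test, n = 24, r = -0.43 without the 2 farthest clones), with r of -0.55 and -0.51 within clones 1 to 13 and 15 to 26. The secondary granule and neutrophil score differed between the sets. Within clones 15 to 26 clones with more neutrophil transcripts as progenitors also had more as monocytes (r = 0.886, rho = 0.936, permutation p = 1e-05, adjusted p = 0.00024 over 24 lists), and r was 0.732 without clones 15, 16, 20 and 21 (n = 7, exact permutation p = 0.0645). Among these 7 clones r fell to 0.281 without the 2 farthest, clones 18 and 19 (exact permutation p = 0.667). Within clones 1 to 13 r was -0.24 (rho = -0.21, permutation p = 0.425), and the difference of 1.13 had a permutation p of 0.00033 (adjusted p = 0.00792 over 24 lists, of which no other passed). Monocyte scores ran only from 0.15 to 0.72 in clones 1 to 13, against -2.04 to 1.03 in clones 15 to 26. A narrow range lowers a correlation, and permuting the sets does not allow for unequal spread. The difference in r therefore cannot be told apart from the difference in range. The mast cell and basophil score had r = 0.813 (rho = 0.709, adjusted p = 0.0216) within clones 15 to 26, and 0.626 without the 2 farthest clones (exact permutation p = 0.0702), and 0.0894 within clones 1 to 13, a difference with a permutation p of 0.0590. Other lists had the higher r in clones 1 to 13. Dendritic cell scores had r = 0.725 there (rho = 0.648, permutation p = 0.00594, adjusted p = 0.143 over 24 lists, r = 0.526 without the 2 farthest clones) and 0.264 in clones 15 to 26. Pattern recognition scores had 0.595 and 0.315, and non-classical monocyte scores 0.568 and 0.246, but in clones 1 to 13 these rested on clones 1 and 9, as r was 0.112 and 0.00105 without them. The differences between the sets had permutation p of 0.231, 0.366 and 0.437 for these 3 lists. The neutrophil scores followed wide ranges of level: S100a8 ran from 237 TPM in clone 22 to 49870 TPM in clone 21 among monocytes, and Ly6g, a neutrophil surface marker, reached 55.8 TPM in clone 20. Clones 15, 16, 20 and 21 are those of clones 15 to 26 with Ly6c2 above 100 TPM as progenitors. In these progenitors a set of 26 abundant monocyte-state genes stood at a median of 1.79%, 1.57%, 7.98% and 4.35% of their level in the monocytes of the same clone. In the other clones this median ran from 0.00538% in clone 6 to 3.14% in clone 22, which had a low progenitor neutrophil score (-0.53). Over the 18 of these genes outside the neutrophil list, the median share went with the progenitor neutrophil score (r = 0.962 and rho = 0.874 in clones 1 to 13, permutation p = 2e-05 and 0.00023, and r = 0.681 and rho = 0.646 in clones 15 to 26, permutation p = 0.0198 and 0.0377, not adjusted). Without the 2 farthest clones r was 0.940 and 0.742. Share and score come from the same progenitor libraries, and the 26 genes include Stfa genes, which go with neutrophil transcripts here. The 2 measures are therefore not independent.

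The series title names a distinct monocyte subset, so the monocyte libraries were also compared with each other. Genes of classical monocytes, non-classical monocytes, macrophages, dendritic cells and the interferon response rose and fell together over the clones. Dendritic cell and macrophage scores had r = 0.865 (rho = 0.907, both permutation p = 1e-05, 0.852 and 0.873 within the sets). Classical monocyte scores went with macrophage (r = 0.840), dendritic cell (0.804) and non-classical scores (0.787), and macrophage with interferon scores (0.736). Non-classical scores had r of -0.00049 with interferon and 0.245 with macrophage scores within clones 1 to 13, and of 0.793 and 0.826 within clones 15 to 26. For classical with interferon scores r was 0.386 and 0.824 within the sets. Primary granule scores followed the cell cycle scores (r = 0.903, rho = 0.837, both permutation p = 1e-05, 0.825 and 0.924 within the sets, 0.838 without the 2 farthest clones). Primary granule scores were lower where interferon scores were higher (r = -0.47, adjusted p = 0.0485, -0.24 and -0.55 within the sets). That relation was weaker by rank (rho = -0.39, permutation p = 0.061) and without the 2 farthest clones (r = -0.32). Cell cycle scores were likewise lower (r = -0.51, adjusted p = 0.0331), a relation that rested on 2 clones, as r was -0.09 without them. Secondary granule and neutrophil scores passed with none of the other 8 lists among monocytes over all clones, with r between -0.21 and 0.360. For some lists the sets differed in sign. With cell cycle scores r was 0.582 within clones 1 to 13 and -0.549 within clones 15 to 26 (permutation p = 0.0391 and 0.0828, not adjusted). With primary granule scores it was 0.194 and -0.545, and with MHC class II scores -0.565 and -0.278. In progenitors the secondary granule and neutrophil score passed with 4 lists. These were primary granule (r = 0.641, adjusted p = 0.00620, 0.386 and 0.731 within clones 1 to 13 and 15 to 26), non-classical monocyte (r = 0.549, adjusted p = 0.0132, 0.791 and 0.355), classical monocyte (r = 0.537, adjusted p = 0.0140, 0.650 and 0.414) and dendritic cell scores (r = 0.463, adjusted p = 0.0408, 0.701 and 0.205). In all, 15 of 36 pairs passed among monocytes.

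**Figure D4:**
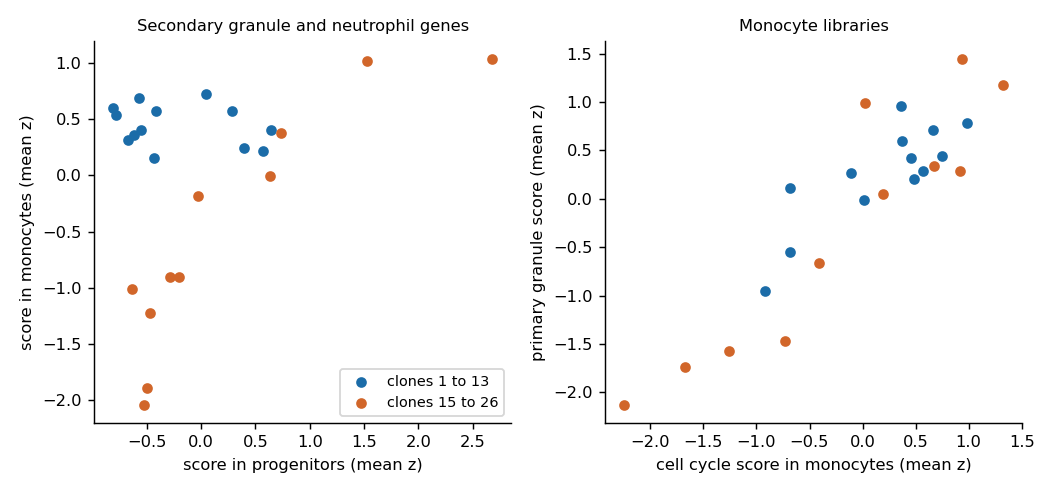
Left, secondary granule and neutrophil score of each clone as progenitor (x axis) and as monocyte (y axis); right, cell cycle score (x axis) and primary granule score (y axis) of the 24 monocyte libraries. Scores are mean z-scores without unit, blue points are clones 1 to 13 and orange points clones 15 to 26; r on the left was -0.24 and 0.886 in these sets, and on the right 0.903 over all clones.

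The last comparison asked in which state clones differed more. Genes with wider spread among monocytes included Ctsg, which kept between 900.0 and 2112 TPM in all progenitors and ran from 1.66 TPM in clone 15 to 1889 TPM in clone 22 among monocytes (SD ratio 7.47, adjusted p = 0.00195). The acetyltransferase subunit Naa10 (SD ratio 8.13), the dUTP hydrolase Dut (6.64), the metallothionein Mt2 (5.67) and the interferon-induced Bst2 (5.63) were also more variable among monocytes. The spectrin Sptbn1 (0.230), Rsrp1 (0.294), Rtf1 (0.296), Cog5 (0.297) and Irf2bp2 (0.311) were more variable among progenitors. Of these, Sptbn1, Rtf1, Cog5 and Irf2bp2 had their lowest progenitor value in clone 24, a library that stood apart. With each set centred Rsrp1 (adjusted p = 0.936) and Irf2bp2 (adjusted p = 0.268) no longer passed. By random swaps of state within clones, 635 of 6329 genes passed, 372 of them wider among monocytes and 263 among progenitors. The direction of this split depended on single clones: it was 358 and 423 without clone 8, 260 and 274 without clone 20, and 240 and 464 without both. It was 154 and 197 among genes with group means within 1 log2 unit, 550 and 539 with a mean of at least 1 TPM and 233 and 79 with at least 20 TPM. It was 747 and 247 without clones 19, 21, 24 and 26, 455 and 38 with each set centred, and 1071 and 249 with rescaled TPM. No state was therefore the more variable one under all settings.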

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

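The tests of the state by set interaction, of the set difference in partner correlation and in the neutrophil score, of Hoxb8 without mitochondrial rows, of unequal spread within the sets, of Ly6c2 and of the share of monocyte-state genes were chosen after the clone sets or the result had been seen, as were the tests without clone 8 or 20 and the 100-draw checks of the state and shared-difference counts.

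Chance was excluded for the 7623 genes changed between states, since 1 of 100 splits, the real one, gave as many and the highest other gave 1807. It was not excluded for the 17 lists that passed camera, since 14 of 100 splits gave as many and the highest other gave 20. That count concerns the ranking of lists against other genes, not the change of their members. By fry the adjusted p was 5.21e-13 for secondary granule and neutrophil genes and 7.74e-16 for stem and progenitor genes. It was 0.0711 for primary granule, 0.120 for mitochondrially encoded and 0.571 for cholesterol synthesis genes. For clone differences shared by both states, 2 of 100 pairings gave as many genes with r above 0.5 as the real 661, with 947 as the highest other, and with each set centred 8 of 100 did, with 380 in the real pairing and 1166 as the highest other. Over all clones few pairings reached the real count, but another pairing exceeded it, so chance was made less likely and not excluded. Those pairings also mixed the sets, so that count includes the difference between the sets. With each set centred chance was not excluded. For unequal spread 2 of 100 swaps gave as many genes as the real 637 (10000 null swaps each), with 779 as the highest other. Chance was made less likely there too, but was not excluded, since another swap gave more genes than the real one.

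The first pattern was a difference between clones 1 to 13 and clones 15 to 26 in how genes changed with state, tested as an interaction. It held for 1268 genes, and 1 of 100 splits of the clones, the real one, gave as many, with 1 gene as the highest other, while without clone 8 it held for 2429 genes and without clones 19, 21, 24 and 26 for 2938. The sets were seen in these same libraries, which favours the real split over random ones. The comparison of splits is therefore not a test of chance. The difference in log2 fold change, clones 15 to 26 minus clones 1 to 13, was -5.08 for Ltf, -4.25 for Stfa1, -3.78 for Gpnmb, -3.74 for Chil3, -3.01 for Hmox1, -2.84 for Clec4n, -2.29 for Cybb, -2.16 for Lyz2, -1.79 for Trem2, -1.55 for Hoxb8, -1.41 for Itgb2, -1.32 for Il1rn, -1.21 for Ccr1, -1.13 for Id2, 1.20 for Ctla2a and 2.25 for Dntt. Without mitochondrial, Gm and pseudogene rows the Hoxb8 difference was -1.49 (SE 0.32, adjusted p = 0.00309), which argues against transcript composition as its whole cause. A batch of culture, library or sequencing may lie behind the sets, but the labels name none, so a batch and a real difference between the clones remain open.

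The second pattern was that partners were found within clones 15 to 26 and at most weakly within clones 1 to 13, where the mean own correlation was 0.0192 (permutation p = 0.191), or 0.0407 without clone 8 (permutation p = 0.0256), a difference from clones 15 to 26 of 0.224 (permutation p = 1e-05, the smallest possible), with a difference of 1.13 in the correlation of the neutrophil score (permutation p = 0.00033). Monocyte neutrophil scores ran only from 0.15 to 0.72 in clones 1 to 13, against -2.04 to 1.03 in clones 15 to 26. The difference in r of that score therefore cannot be told apart from the difference in range. Without clones 20 and 21 the neutrophil score kept r = 0.864 within clones 15 to 26 (exact permutation p = 0.00229), so these extreme clones were not the whole cause of its r there. Without clones 15 and 16 as well r was 0.732 (exact permutation p = 0.0645), and 0.281 with clones 18 and 19 also left out (exact permutation p = 0.667). The progenitor score also went with the share of other abundant monocyte-state genes (r = 0.681), so mature cells in the progenitor cultures remain open. Clone numbers crossed between the states in clones 1 to 13 were neither seen nor excluded. The best pairing found on 500 genes had a mean correlation of 0.0711 (SD 0.0145 over 100 gene draws) on the other 500. It was 0.117 and 0.0949 for pairings between the sets, which cannot be partners, and 0.240 within clones 15 to 26. Without clone 8 it was 0.0602 against 0.119 and 0.0727. Pairings between the sets hold clones 15 to 26, which differ more from each other, so crossed partners in clones 1 to 13 could also fall below them. The share of 53.9% in mutual best matches decided nothing, as unrelated profiles give 52%. Smaller differences between clones 1 to 13 may contribute, since their median SD over genes was 0.498 of that of clones 15 to 26 in progenitors and 0.624 in monocytes. This stays open, because without clones 8, 19, 21, 24 and 26 the SD in clones 1 to 13 and 15 to 26 was 0.313 and 0.252 in progenitors and 0.332 and 0.620 in monocytes, and all 7 remaining clones of 15 to 26 matched their own partner, and no biological explanation was tested.

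The third pattern was Ly6c2 above 100 TPM in 5 progenitor libraries: 198 TPM in clone 1, 194 in clone 15, 129 in clone 16, 468 in clone 20 and 975 in clone 21, where it was 220% of the level in the monocytes of that clone. Progenitor clone 21 stood apart as a library, with 23247 genes at 0 and a highest correlation of 0.813 with any library. Mature cells in these 5 cultures would bring other abundant monocyte-state transcripts at a like share of their monocyte level. The Ly6c2 share was at least 5.70 times the median share of 26 such genes in each of these libraries, and none of the 26 reached it. This argues against cells with the make-up of the same clone's monocyte culture as the whole cause. The 26 genes were picked for a high monocyte level and a large rise over all clones, which favours a low share. Ly6c2 meets the same rule, with a log2 fold change of 6.07. The libraries were picked by their Ly6c2 level, which favours a high share. The size of the ratio depends in part on these picks. In the other progenitor libraries the ratio to the median ran from 0.0391 in clone 22 to 267 in clone 11. Mature cells of another make-up, rich in Ly6c2 and poor in the 26 genes, remain open. Reads shared with Ly6c1 and an early onset of Ly6c2 in these progenitors remain open and were not tested.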

How the results depend on the processing

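Of the settings below, the clone subsets (clones 8 and 20 left out included), the centring of the sets and the removal of rows were chosen after seeing the data. Genes changed between states stayed between 5407 and 10926 under the planned settings and fell to 5005 in clones 15 to 26 alone. In clones 1 to 13 alone they numbered 7936, so testing fewer clones does not by itself account for the fall. At least 2-fold changes numbered 1826 with a pseudocount of 5, which shrinks folds by construction. With no replicate block 7436 genes and 17 lists passed, and the call of 1 named gene, Hoxb8, was lost (adjusted p = 0.116). No list passed camera with an estimated correlation (0), against 15 to 17 in the other settings. Named genes between states gave 769 results with the same call, 6 weaker and 1 reversed: Hoxb8 at -0.28 in clones 15 to 26 alone.

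The count of genes with shared clone differences (353) was 177 with a mean of at least 5 TPM, 540 without a filter, 1047 with rescaled TPM, 219 by Spearman correlation, 959 without the cell cycle score and 217 without the first principal component. It was 32 with each set centred, 0 in clones 1 to 13 (477 at an unadjusted p under 0.05, about as many as chance gives), 23 in clones 15 to 26, 613 without clones 19, 21, 24 and 26, and 7 with both that and centring. Apart from the smaller samples and changed filters, the cause was not tested. Correlations that turned negative in clones 1 to 13 were those of S100a11 (-0.492), S100a9 (-0.394), Stfa2 (-0.270), Pgk1-rs7 (-0.245), Itgb2l (-0.236), Ddit3 (-0.230), Slpi (-0.172), Ldha (-0.0924), Map7 (-0.0634) and Tmsb4x (-0.0166). Pgk1 turned negative in clones 15 to 26 (-0.153), and Pgk1-rs7 with the sets centred (-0.189) and with clones 19, 21, 24 and 26 also left out (-0.191). Pgk1-rs7 gave no value in clones 15 to 26, where all progenitors were listed at 0. Named shared genes gave 213 results with the same call and 134 weaker.

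The number of list scores shared by both states was 2 with rescaled TPM and 1 with each set centred, against 0. Own partners numbered 6 to 10 over all settings, and pairs of lists among monocytes 11 to 17. Genes of unequal spread (635) were 312 with a mean of at least 20 TPM, 1089 with at least 1 TPM, 1320 with rescaled TPM, 351 where group means lay within 1 log2 unit and 994 without clones 19, 21, 24 and 26. The cause was not tested beyond the numbers of genes entered. Depth was unknown, so its effect could not be assessed.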

Other observations

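The values of single clones below were looked at after the comparisons were done, and the test on the degree of maturation was written before its result was seen. Single monocyte libraries held high levels of genes of particular programmes. Monocyte clone 15 had 1948 TPM of Irf7 and 577 TPM of Isg15, interferon-induced genes with medians of 26.7 and 13.1 TPM over the 24 monocyte libraries, while its progenitors had 1.48 TPM of Isg15. Mcpt8, a basophil protease, reached 1530 TPM in monocyte clone 19 where the median was 18.04 TPM, and it was at 523 TPM in the progenitors of that clone. Prg2, an eosinophil granule protein, reached 1053 TPM in monocyte clone 18, 943 TPM in clone 11 and 907 TPM in clone 24. Cd74, the invariant chain of MHC class II, ran from 0.686 TPM in monocyte clone 9 to 175 TPM in clone 5.

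Some progenitor libraries held neutrophil transcripts. S100a8 was at 3502 TPM in progenitor clone 20 and 2191 TPM in clone 21, against a median of 3.65 TPM over the 24 progenitor libraries, and these clones had 41618 and 49870 TPM as monocytes. Stfa2 was at 76.5 and 103 TPM in the same progenitor libraries and at 7974 and 9245 TPM in their monocytes. In these libraries S100a8 stood at 8.41% and 4.39% of its monocyte level, and Stfa2 at 0.960% and 1.11%. The medians over 26 abundant monocyte-state genes were 7.98% and 4.35%. S100a8 and Stfa2 are among these 26 genes, whose shares reached 26.5% in clone 20 and 39.6% in clone 21. The closeness of S100a8 to the medians therefore cannot decide whether mature cells were present. Some mature cells in these progenitor cultures were not excluded as the source of S100a8. At the other end, S100a8 was at 0.133 TPM in progenitor clone 22, whose monocytes had 237 TPM of S100a8 and 4796 TPM of the primary granule gene Mpo.

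Pgk1-rs7 parted the sets of clones almost without exception. It was above 0 in all 13 progenitors and in 12 of 13 monocytes of clones 1 to 13, and listed at 0 in all 11 progenitors and in 10 of 11 monocytes of clones 15 to 26. The exceptions were monocyte clone 8, listed at 0, and monocyte clone 20, at 50.5 TPM. Pgk1 itself had a mean of 319 TPM (SD 63.2, n = 13) in progenitors of clones 1 to 13 and of 173 TPM (SD 27.7, n = 11) in those of clones 15 to 26. Pgk1 in these monocyte libraries went with their sets: it was 413 TPM in clone 8, the highest of clones 1 to 13, and 191 TPM in clone 20, where clones 15 to 26 reached at most 216 TPM. Reads of the pseudogene assigned to Pgk1 in monocyte clone 8 therefore remain open. Other genes did not all go with the sets. On a scale with 0 at the monocyte mean of clones 1 to 13 and 1 at that of clones 15 to 26, over the 200 genes that parted the other monocyte libraries most (Pgk1 and Pgk1-rs7 left out), monocyte clone 8 scored 0.707. The other monocytes of clones 1 to 13 scored -0.05 to 0.132, and those of clones 15 to 26 scored 0.474, in clone 20, to 1.13. Over the 1000 most variable genes monocyte clone 20 correlated best with its own progenitor (r = 0.288) and had r = -0.06 with progenitor clone 8. Monocyte clone 8 had r = -0.22 with its own progenitor, which ranked 23 of 24, and 0.143 with progenitor clone 20. Monocyte clone 8 also stood apart as a library, with 11.1% of its TPM in mitochondrial transcripts, where the next highest monocytes of clones 1 to 13 had 6.83%. It had 9461 genes with at least 1 TPM, the fewest of the monocytes of that set, and a highest correlation of 0.922 with any library. A wrong label or an outside library for monocyte clone 8 also remains open. The effect of its differing make-up on the score of 0.707 was not tested. Without both clones 7451 genes changed between states, and 374 genes shared their clone differences between states, 270 of them among the 353.

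Primary granule scores followed cell cycle scores among monocytes (r = 0.903). One hypothesis is that clones had matured to different degrees, in which case stem and progenitor scores would also follow the cell cycle scores in both sets. Within clones 15 to 26 they did (r = 0.679, rho = 0.755, permutation p = 0.0239 and 0.00986, r = 0.721 without the 2 farthest clones), and within clones 1 to 13 r was 0.0538 (rho = -0.23, permutation p = 0.865 and 0.447). Ribosome biogenesis scores had r of 0.781 and -0.21. Without the 2 farthest clones r in clones 1 to 13 was -0.57 for the stem and progenitor scores (permutation p = 0.0633) and -0.74 for the ribosome biogenesis scores (permutation p = 0.0120), which runs against the hypothesis there. Different degrees of maturation may hold for clones 15 to 26, while the test over both sets stayed undecided.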
